A study of Mus musculus with 12 samples.

How the data were processed

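Liver RNA of 12 male C57BL/6 mice was measured on Affymetrix expression arrays, 1 array per mouse. Per the labels, 6 mice received low-dose penicillin in the drinking water after weaning, 6 received none, and livers were taken after 7 weeks of intervention. Total RNA was extracted with a column kit and labelled with biotin by a kit that copies transcripts from their 3-prime ends, per the labels' protocols. The dose of penicillin, the hour of collection and the order of processing were not given in the sources used here.

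The deposited values are probeset intensities made by the authors with RMA, per the submitters' processing notes. The software, its version and its settings were not given in the sources used here. RMA subtracts background, makes the distributions of all arrays alike and combines the probes of a probeset, so a change shared by most genes would be removed from these values. RMA usually returns log2 values, but the deposited intensities were on a linear scale, and log2 was therefore taken here before any test. The planned test took the values to be log2 and provided for this step where they were linear. No further normalization was applied.

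The table held 45101 probesets, of which 64 were hybridisation or labelling controls. Of the 45037 others, 34945 had 1 gene in the platform annotation, 932 had several and 9160 had none there. No gene was named from a probeset with several. Symbols were updated through the gene identifier with a RefSeq gene table of assembly GRCm38.p6, in which 18033 identifiers were found and 162 were not; the annotation's own symbol was kept for the latter. Probesets whose mean over the 12 arrays was under the median of all probesets other than controls (4.73 on the log2 scale) were left out, which left 22519. Of these, 2613 had no single gene and were not tested as genes. Each gene was represented by its probeset with the highest mean, giving 11899 genes. Named probesets can share sequence with close relatives of a gene, and a level on 1 probeset cannot be set against that of another. The files hold no detection calls, so a low level cannot be told from background.

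The comparison was penicillin minus control, with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes variances, no trend, two-sided) and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. A total of 20 gene lists and 12 lists of cell type markers were fixed before the data were examined, as were the test, the filter, the choice of probeset and the rule for named genes. Of the 607 genes listed, 540 were named by at least 1 probeset. The 31 lists with at least 3 measured members were tested with limma's camera, which asks whether a list moved against the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists. Members past the threshold were counted over all genes tested and also with p-values adjusted over the list alone. Camera with a correlation estimated for each list, and fry, which tests each list on its own, were run as alternatives. The 95% intervals of list means came from the mean of each list's members per array. Array measures were compared by an exact permutation test over all 924 assignments of 6 arrays to a group, two-sided, with a smallest possible p of 0.00216. The same exact test was applied to list means after the data were seen.

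The genes named were, by the rule, the 10 with the smallest p in each direction where fewer than 10 passed, 2 members of each list with the smallest p where fewer than 2 passed (optional for a list that neither passed nor held a gene that did), and 10 genes chosen in advance (Fasn, Acaca, Scd1, Srebf1, Cyp7a1, Cyp8b1, Cyp2b10, Cyp3a11, Saa1 and Hamp). List members named because they passed over the list alone, and any other member named beyond these, were chosen after their values were seen. The alternatives tried were other filters on dim probesets, repeated quantile normalization, centring on array medians, the replicate number as a block, array weights, other variance priors, other ways of summarising probesets, other thresholds and the omission of each array. Fits with a clock score or an immediate early gene score as a covariate, and fits without arrays that stood apart, were added after the data were seen.

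The tests were run on simulated data with the spread of these arrays. With 50 of 11899 genes changed at each fold size, 88% were recovered at 1.5-fold, 92% at 2-fold and 100% at 3-fold and at 4-fold, with 11 false calls. The changed genes were drawn at random, and all sizes were changed in 1 run, which eases the adjusted threshold. Recovery can be lower for a variable gene or where few genes change. In the real comparison 41 genes differed by more than 1 on the log2 scale, and 0 genes passed. Of 31 simulated lists, all 3 that were shifted by 0.3 on the log2 scale were recovered, and 0 of the other 28 were called. The simulated noise of each gene was drawn on its own, so genes of a list did not move together. These 0 calls therefore cannot show how camera's preset correlation behaves where genes do move together.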

Results

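The series asked how low-dose penicillin, given in drinking water to young mice, affects the animals, in a study concerned with gut bacteria and body fat. The liver part analysed here held 6 control and 6 penicillin-treated males of the inbred strain C57BL/6 after 7 weeks of intervention, 1 array each. Any 2 arrays correlated at 0.980 to 0.997 over genes. The closest pair, control 1 and control 3, had a median absolute difference of 0.10 on the log2 scale, as did the next pair, against 0.19 for the most distant. No array was therefore taken as a copy of another, and each was counted as its own sample. No label gives the cage of a mouse. Mice that shared a cage and its drinking water would not be independent, as the tests here assume. An effect of cages could not be told from that of penicillin. By exact permutation tests between the groups, the exact p was 0.716 for the 3-prime minus 5-prime signal of Gapdh, 0.669 for that of beta-actin and 0.147 for the first principal component, with adjusted p of 0.736 or more. The median level and the interquartile range had been made nearly alike by the deposited normalization and say nothing about quality.

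The comparison of penicillin with control asked which liver genes differed after the treatment. As lists, genes of fatty acid oxidation, triglyceride storage, lipogenesis and drug metabolism were higher in penicillin livers, along with genes of the interferon response and of antigen presentation. Lists of immediate early, heat shock, endoplasmic reticulum stress, acute phase, innate sensing and cholesterol synthesis genes were lower, as were markers of cholangiocytes and of Kupffer cells. In all, 14 of 31 lists passed with camera's preset correlation, 6 higher and 8 lower. None held with an estimated correlation (0 lists, smallest adjusted p = 0.184, 6 lists at an unadjusted p under 0.05), and 0 passed with fry. No single gene passed: limma called 0 of 11899 genes, with a smallest adjusted p of 0.265. A total of 950 genes had an unadjusted p under 0.05, 515 higher and 435 lower, where 595 would be reached by chance, and limma without its variance prior also called 0. The median absolute log2 difference over all genes was 0.07, beside a median standard error of 0.09. Control 1, control 3 and control 5 stood apart by high immediate early genes. Without these 3 arrays 488 genes had an unadjusted p under 0.05, 0 passed, and 11 lists passed, 4 higher and 7 lower. Of these, 3 had not passed with all arrays: one-carbon and choline metabolism as higher (adjusted p = 0.0225), and markers of stellate cells and fibroblasts (adjusted p = 0.00385) and of endothelial cells (adjusted p = 0.0185) as lower. With the immediate early gene score as a covariate 545 genes had an unadjusted p under 0.05, 0 passed, and 10 lists passed, among them the same 3 (adjusted p = 0.00817, 0.0162 and 0.0300). The immediate early list is not among the 10, since the score is its own mean. The calls of lipogenesis, interferon, antigen presentation, innate sensing, heat shock and endoplasmic reticulum stress ended, and that of cholesterol synthesis turned from lower to higher.

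The single genes with the smallest p in each direction did not pass. On the higher side, Mup10, one of a family of near-identical major urinary proteins, stood at 10.98 ± 0.12 in log2 intensity with penicillin and 10.49 ± 0.16 in controls (SD, n = 6), a difference of 0.49 (SE 0.08, adjusted p = 0.265). Fabp2, a fatty acid binding protein best known from the intestine, was higher by 0.48, and Car5a, a mitochondrial carbonic anhydrase, by 0.34. Dhrs4, Zfp809, Dglucy, 9130409I23Rik and the bile acid and conjugate exporter Abcc3 were higher by 0.28 to 0.91. The other members of this group were Tlr5, the receptor of bacterial flagellin, and Cyp2b10. On the lower side, Vasn differed by -0.72 (SE 0.13, adjusted p = 0.265), and the ubiquitin ligase Rnf20 by -0.27. Klf6, Sall1, Mtmr12, Nfxl1 and the transcription factor Gata6 differed by -0.34 to -0.75. Ptgds, a prostaglandin D synthase, differed by -0.51, Eif2ak3, which encodes the stress kinase PERK, by -0.83, and S100a9 by -1.63. Adjusted p-values of these genes ran from 0.265 to 0.304. All 6 penicillin arrays lay above all controls for Mup10, Fabp2, Car5a, Dhrs4, Zfp809, Dglucy and Abcc3, and below all controls for Vasn, Rnf20, Klf6, Sall1, Mtmr12 and S100a9. Genes named for a small p, here and in the lists below, tend to separate the groups through that choice. Such separation is no added support.

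Genes of fatty acid breakdown stood higher together in penicillin livers. Of 28 measured members of the list of fatty acid oxidation genes and targets of the nuclear receptor PPAR-alpha, 26 were higher and 2 lower, and the list rose by a mean of 0.26 on the log2 scale (95% interval 0.05 to 0.47; camera adjusted p = 3.25e-11, adjusted p = 0.184 with an estimated correlation). In this list 7 members passed adjusted over the list alone, against 0 over all genes. Among them were Ech1, an enoyl-CoA isomerase, at 12.22 ± 0.10 against 11.97 ± 0.12 in controls (SD, n = 6), and Eci1, of similar activity, higher by 0.29 (SE 0.08). The others were Decr1 (0.20) and Acadl (0.17), both enzymes of beta-oxidation, the acyl-CoA thioesterase Acot2 (0.37), the peroxisomal protein Pex11a (0.49) and the pantetheinase Vnn1 (0.93). The immediate early genes described further on differed between the same groups, and with their score as a covariate the mean of this list was 0.15. Without control 1, control 3 and control 5 it was 0.17.

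Genes of triglyceride synthesis and lipid droplets also stood higher. Of 21 measured, 15 were higher and 6 lower, with a mean of 0.25 (95% interval 0.09 to 0.41; camera adjusted p = 2.07e-04, adjusted p = 0.184 with an estimated correlation). Of them, 2 passed adjusted over the list alone, against 0 over all genes. Fitm1, a lipid droplet protein, was at 10.81 ± 0.32 with penicillin and 10.19 ± 0.19 in controls (SD, n = 6), 1.53-fold higher with every penicillin array above every control. Pparg, a nuclear receptor that drives fat storage, was 1.55-fold higher (log2 difference 0.63, SE 0.17). The list of de novo lipogenesis rose by a mean of 0.16, with 14 of 17 members higher (95% interval -0.05 to 0.38; camera adjusted p = 0.00762, adjusted p = 0.436 with an estimated correlation). Its call ended without penicillin 2 (mean 0.11, adjusted p = 0.148) or penicillin 5 (mean 0.12, adjusted p = 0.057), and without control 1, control 3 and control 5 (mean 0.08). Thrsp, a lipogenic gene responsive to thyroid hormone, was the 1 member that passed adjusted over the list alone, against 0 over all genes. It was 1.76-fold higher, at 13.25 ± 0.37 against 12.44 ± 0.49 (SD, n = 6). Srebf1, the transcription factor of lipogenesis, was higher by 0.51 (SE 0.21, adjusted p = 0.593). Enzymes of the pathway gave smaller differences: Fasn 0.09 (SE 0.19), Acaca 0.02 (SE 0.07) and Scd1 -0.14 (SE 0.16), none of which passed. These rested on single arrays: without penicillin 2 Fasn was at -0.043 and Acaca at -0.021, and without penicillin 1 Scd1 was at -0.0012.

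Genes that respond to drugs and other foreign compounds through the receptors CAR and PXR stood higher. Of 22 measured, 18 were higher and 4 lower, with a mean of 0.20 (95% interval 0.07 to 0.32; camera adjusted p = 2.07e-04, adjusted p = 0.184 with an estimated correlation). Cyp2b10, the classic CAR target, was 2.82-fold higher, at 8.27 ± 0.57 with penicillin and 6.77 ± 0.71 in controls (SD, n = 6). It was the 1 member that passed adjusted over the list alone, against 0 over all genes (log2 difference 1.5, SE 0.33, adjusted p = 0.304). The name of its probeset carries a suffix that marks probes shared by several transcripts. Aldh1a1, a retinal dehydrogenase, was higher by 0.14 with every penicillin array above every control, and the PXR target Cyp3a11 by 0.28 (SE 0.13, adjusted p = 0.619). Without control 6, penicillin 1, penicillin 5 and penicillin 6, whose clock genes stood apart, the list mean was 0.15 and did not pass (adjusted p = 0.0547).

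**Figure D1:**
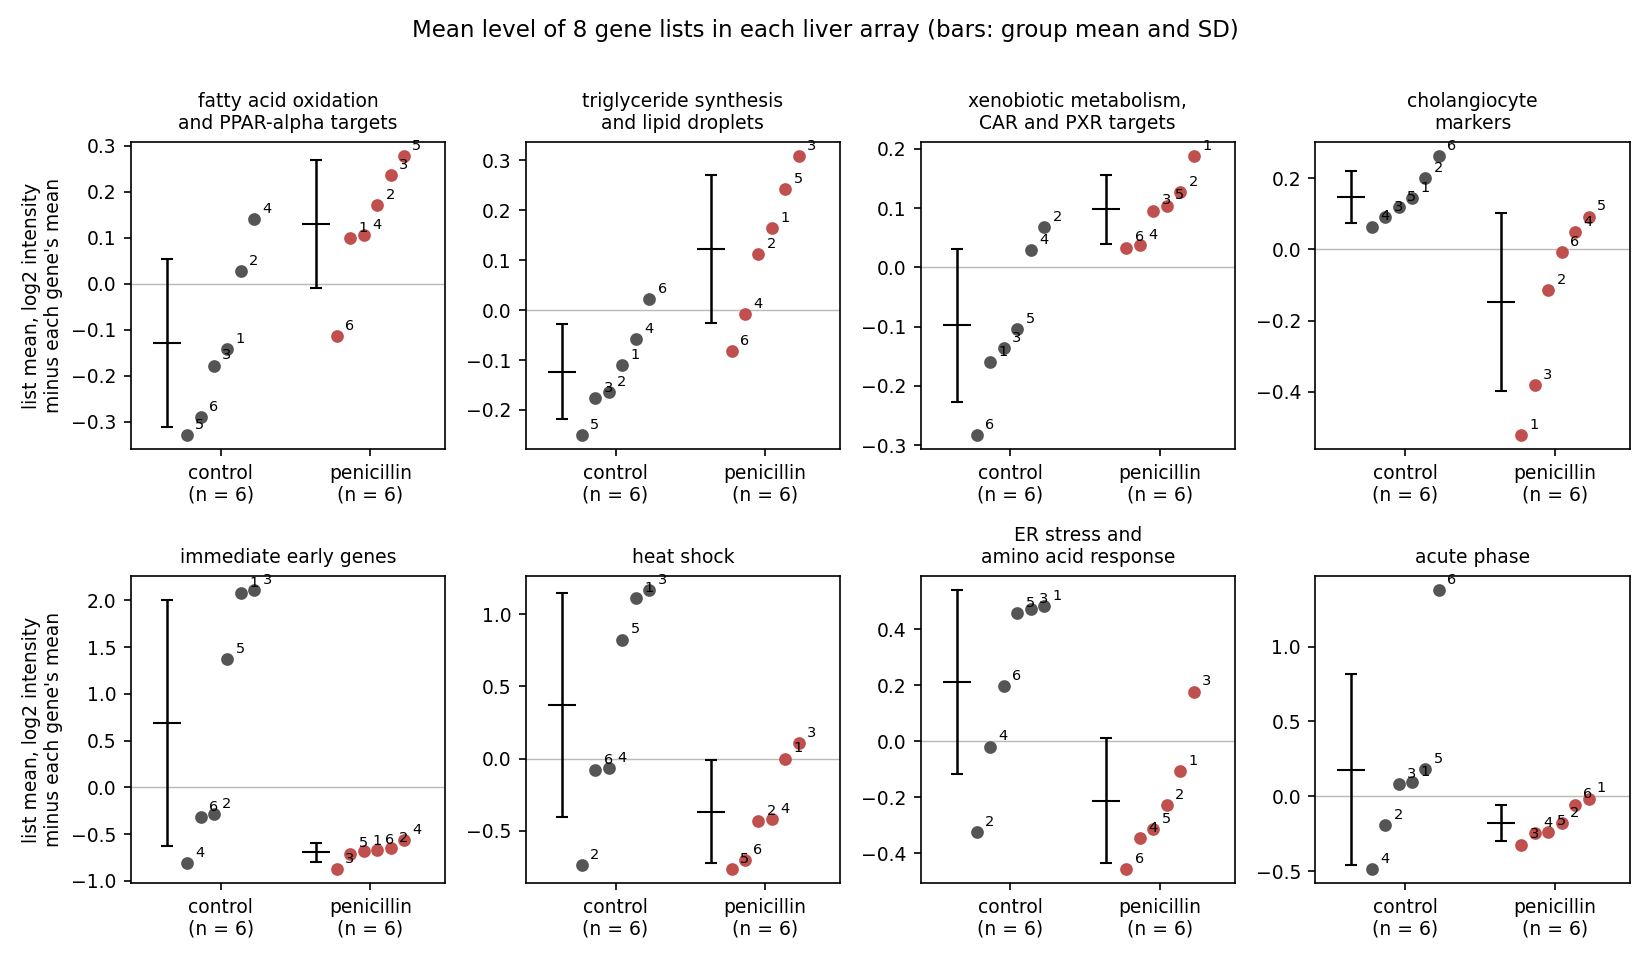
Mean level of 8 gene lists in each of the 12 arrays, as log2 intensity after subtraction of each gene's mean over all arrays; points are arrays numbered by replicate, and bars give the group mean and SD. Controls 1, 3 and 5 lie at 1.38 to 2.11 for immediate early genes, where the penicillin arrays lie between -0.88 and -0.57, and control 6 lies at 1.38 for acute phase genes.

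Of the lists of cholesterol, bile acid and lipoprotein genes, 1 passed. The list of cholesterol synthesis was lower, with 16 of 20 members lower and a mean of -0.11 (95% interval -0.42 to 0.21; camera adjusted p = 0.0434, adjusted p = 0.688 with an estimated correlation), led by Sqle (-0.33) and Mvd (-0.43, or -0.25 without penicillin 1), neither of which passed, adjusted over the list alone (0 of 20) or over all genes. This call rested on single arrays: it ended without control 1, 2, 3, 5 or 6 or penicillin 1, 3 or 5 (adjusted p from 0.118 to 0.242), and the mean was -0.21 without control 4, -0.18 without penicillin 2 and -0.06 without penicillin 1. The mean was 0.05 without control 1, control 3 and control 5, and with the immediate early gene score as a covariate the list passed in the opposite direction, as higher, with a mean of 0.10 (adjusted p = 0.0396). Array weights (adjusted p = 0.0868) and the replicate block (adjusted p = 0.0748) also ended the call. The list of bile acid synthesis and transport did not pass (15 of 26 higher, mean 0.02, or -0.0091 without control 6, adjusted p = 0.696), but 2 members passed adjusted over the list alone, against 0 over all genes. Abcc3 was higher by 0.28 (10.76 ± 0.07 against 10.47 ± 0.10, SD, n = 6), and Cyp39a1, an oxysterol hydroxylase, differed by -0.72 (8.26 ± 0.20 against 8.98 ± 0.49). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and Cyp8b1, needed for cholic acid, were higher by 0.39 (SE 0.29) and 0.35 (SE 0.22) without passing, and by 0.63 and 0.20 without control 6. The list of lipoproteins and lipid uptake did not pass (adjusted p = 0.638), with a mean of -0.04 (-0.02 without penicillin 3, -0.026 without penicillin 1 and -0.068 without penicillin 5), a median of 0.01 and a test direction of lower. Its members with the smallest p, the lipase Lpl (-0.63, SE 0.23) and the lipoprotein receptor Scarb1 (-0.29, SE 0.10), did not pass.

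Immediate early genes, which are induced within minutes by many stimuli, were lower in penicillin livers. All 13 measured members were lower, and the list fell by a mean of 1.38 on the log2 scale (95% interval -2.58 to -0.19; camera adjusted p = 7.09e-12, adjusted p = 0.184 with an estimated correlation). Of them, 11 passed adjusted over the list alone, against 0 over all genes. Fos was 8.18-fold lower, at 6.19 ± 0.34 with penicillin and 9.22 ± 2.51 in controls (SD, n = 6), and Klf6 1.68-fold lower, at 6.67 ± 0.08 against 7.42 ± 0.37. The others were Egr1, Btg2, Junb, Ier2, Atf3, Ier3, Jun, Zfp36 and Gadd45g, with differences of -0.75 to -2.80. The controls were not alike: the list mean stood at 2.08, 2.11 and 1.38 in control 1, control 3 and control 5 and at -0.81 to -0.29 in the others. Without these 3 arrays the mean was -0.22 (adjusted p = 0.0196), and Atf3, at -1.23 with all arrays, turned to 0.046.

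Stress genes moved with the immediate early genes across the same arrays. All 18 members of the list of endoplasmic reticulum stress and the amino acid response were lower, with a mean of -0.42 (95% interval -0.79 to -0.06; camera adjusted p = 5.39e-09, adjusted p = 0.184 with an estimated correlation). Dnajb9 and Manf, both induced by unfolded protein in the endoplasmic reticulum, differed by -0.80 (SE 0.24) and -0.66 (SE 0.21). All 11 heat shock genes were lower, with a mean of -0.74 (95% interval -1.52 to 0.04; camera adjusted p = 8.77e-07, adjusted p = 0.397 with an estimated correlation), among them the chaperones Hspa1b (-1.41, SE 0.55) and Hsph1 (-1.08, SE 0.44). Adjusted over the list alone 0 members of either list passed, and 0 over all genes. Without control 1, control 3 and control 5 the mean was -0.16 for endoplasmic reticulum stress (adjusted p = 0.0308) and -0.07 for heat shock (adjusted p = 0.922). With the immediate early gene score as a covariate neither call held, at adjusted p = 0.106 and 0.666.

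**Figure D2:**
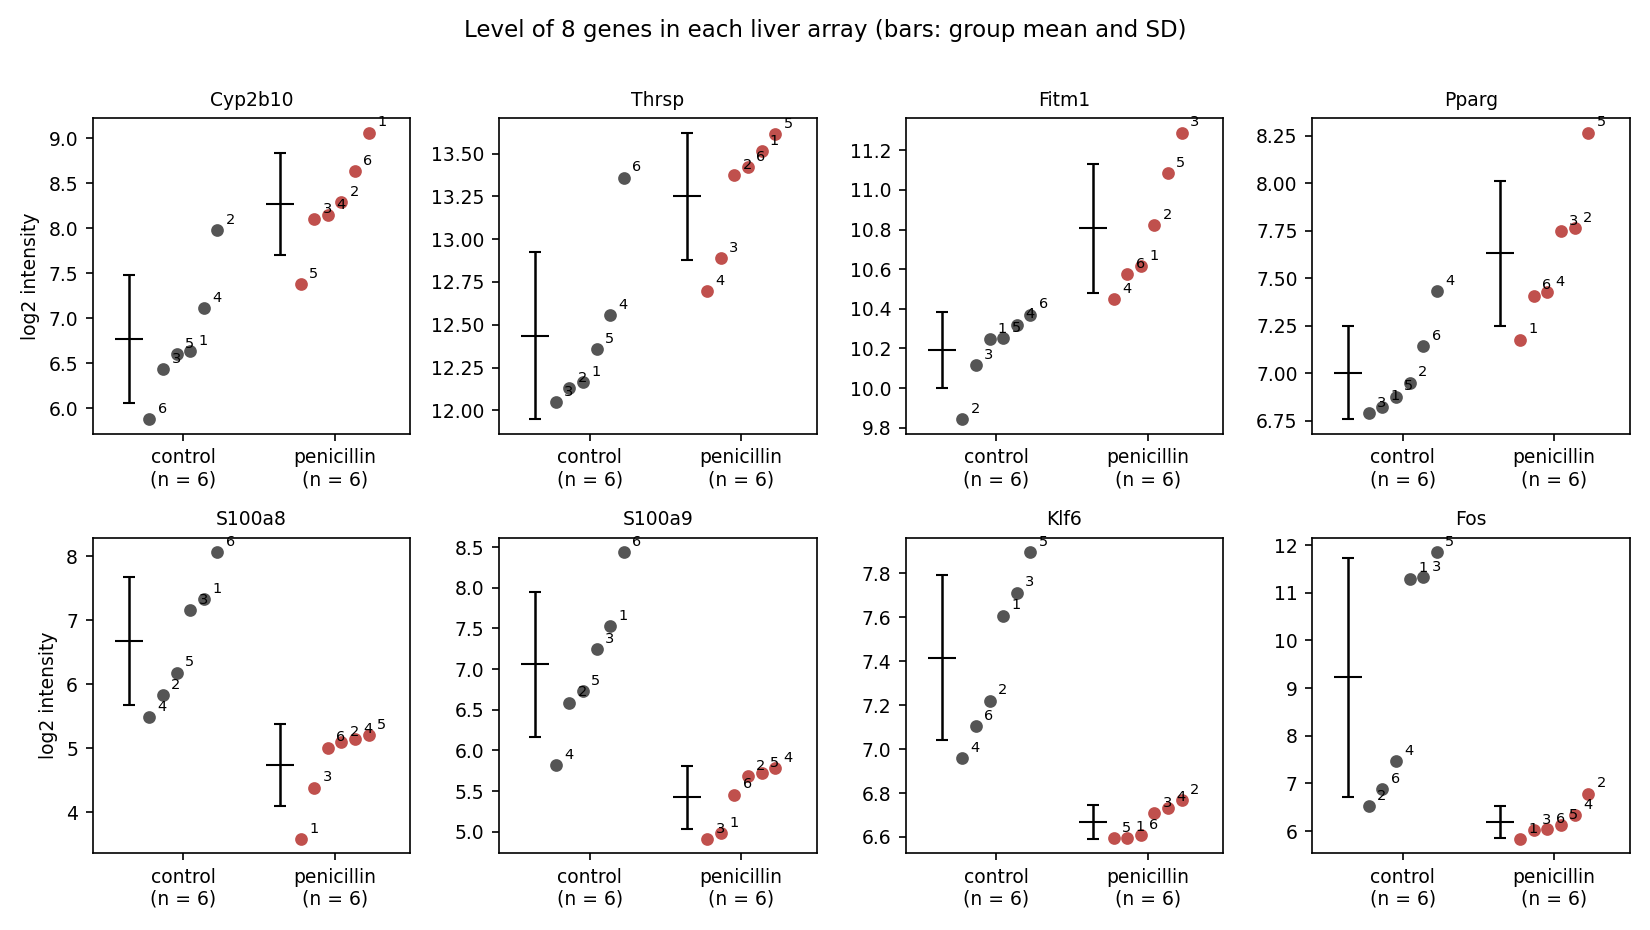
Level of 8 genes in each of the 12 arrays, as log2 intensity of the probeset with the highest mean; points are arrays numbered by replicate, and bars give the group mean and SD. All penicillin arrays lie above all controls for Fitm1 and below all controls for S100a8, S100a9 and Klf6, and the control arrays of Fos fall into high and low values.

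Acute phase and innate immune genes were lower, though single arrays carried much of this. Of 28 acute phase genes, 25 were lower, with a mean of -0.35 (95% interval -0.94 to 0.24; camera adjusted p = 1.18e-05, adjusted p = 0.436 with an estimated correlation). Control 6 stood at 1.38 for this list, and without it the mean was -0.11 (adjusted p = 0.103), while without control 6, penicillin 1, penicillin 5 and penicillin 6 it was -0.19 (adjusted p = 0.0525). The plasma protein Crp differed by -0.19 (SE 0.07) and the lipopolysaccharide co-receptor Cd14 by -0.40 (SE 0.15). Saa1, serum amyloid A, stood at 9.97 ± 0.32 with penicillin and 10.52 ± 1.83 in controls (SD, n = 6; adjusted p = 0.888), a difference of -0.56 that turned to 0.12 without control 6. Hamp, which encodes the iron hormone hepcidin, was higher by 0.10, by 0.04 without penicillin 6 and by 0.18 without penicillin 5. Of these genes 0 passed, adjusted over the list alone or over all genes. Of 17 innate sensing genes and targets of NF-kappaB, 14 were lower, with a mean of -0.20 (95% interval -0.39 to -0.0052; camera adjusted p = 0.0364, adjusted p = 0.397 with an estimated correlation). Adjusted over the list alone 2 members passed, against 0 over all genes, and they moved apart: the adhesion molecule Icam1 differed by -0.46 (SE 0.14) and Tlr5 was higher by 0.62 (SE 0.13). The call of this list ended without control 2, control 5, control 6, penicillin 1, penicillin 3, penicillin 4 or penicillin 5 (adjusted p from 0.055 to 0.126), without control 1, control 3 and control 5, without control 6, penicillin 1, penicillin 5 and penicillin 6, and with no filter, a stricter filter or array weights.

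Interferon and antigen presentation genes stood higher. Of 22 interferon response genes, 18 were higher, with a mean of 0.20 (95% interval -0.17 to 0.57; camera adjusted p = 0.00341, adjusted p = 0.643 with an estimated correlation), led by the guanylate binding protein Gbp6 (0.93, SE 0.29) and the peptide transporter Tap1 (0.45, SE 0.15). Of 6 genes of antigen presentation by MHC class II, 5 were higher, with a mean of 0.32 (95% interval -0.02 to 0.66; camera adjusted p = 0.00131, adjusted p = 0.403 with an estimated correlation), among them the invariant chain Cd74 (0.28, SE 0.11) and H2-Aa (0.44, SE 0.18). Adjusted over the list alone 0 members of either list passed, and 0 over all genes. Both lists were lowest in control 1 and control 3, at -0.45 and -0.48 for interferon and -0.54 and -0.58 for MHC class II. Markers of B and plasma cells, which carry MHC class II, were also lowest in these 2 arrays, at -0.43 and -0.40, and had a group difference of 0.18 that did not pass. Without control 1 the interferon mean was 0.13 (adjusted p = 0.088), without control 3 it was 0.13, and without control 1, control 3 and control 5 the means were -0.03 and 0.08, neither of which passed.

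Among markers of other liver cells, those of cholangiocytes, the cells lining bile ducts, were lower. All 6 measured were lower, with a mean of -0.29 (95% interval -0.53 to -0.06; camera adjusted p = 8.35e-04, adjusted p = 0.184 with an estimated correlation), among them Sox9 (-0.55, SE 0.19) and the keratin Krt19 (-0.36, SE 0.13). With penicillin Sox9 stood at 5.23 ± 0.29 and Krt19 at 5.29 ± 0.33 (SD, n = 6). These levels lay not far above the filter of 4.73, where background can limit how low a level is read. The list stood at -0.52 in penicillin 1 and -0.38 in penicillin 3, against -0.11 to 0.09 in the other penicillin arrays, and markers of stellate cells and fibroblasts were lowest in the same 2 arrays, at -0.41 and -0.35. Of markers of Kupffer cells and macrophages, 13 of 16 were lower, with a mean of -0.09 (95% interval -0.33 to 0.14; camera adjusted p = 0.0125, adjusted p = 0.643 with an estimated correlation), led by the lysozymes Lyz2 (-0.23, SE 0.08) and Lyz1 (-0.22, SE 0.11). The call ended without control 2 (mean -0.06, adjusted p = 0.177), control 6 (mean -0.02, adjusted p = 0.522) or penicillin 3 (mean -0.04, adjusted p = 0.227) and with array weights (mean -0.03, adjusted p = 0.317), while the mean was -0.20 without control 1, control 3 and control 5. Adjusted over the list alone 0 members of either list passed, and 0 over all genes.

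Of 12 neutrophil markers listed only S100a8 and S100a9, which form the calcium-binding protein calprotectin, were measured above the filter, too few for a list test. S100a8 was lower, at 4.74 ± 0.64 with penicillin and 6.68 ± 0.99 in controls (SD, n = 6; SE 0.42, adjusted p = 0.304). Its penicillin level lay near the filter of 4.73, where background limits how low a level can be read, so no fold is given. S100a9 was also lower, at 5.42 ± 0.38 against 7.06 ± 0.90 (SD, n = 6; SE 0.35, adjusted p = 0.299). For both, all 6 penicillin arrays lay below all 6 controls. Both passed adjusted over the list alone, against 0 over all genes.

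The other lists did not pass. Genes of gluconeogenesis and the insulin response had a mean of -0.21 (adjusted p = 0.0822) but a median of -0.06, with 8 of 18 higher and 10 lower. Igfbp1 stood at -1.53 (SE 0.54) and Irs2 at -0.61 (SE 0.23), both far below that median. The list would have passed without control 4 (adjusted p = 0.019) or penicillin 1 (adjusted p = 0.0053), without control 6, penicillin 1, penicillin 5 and penicillin 6 (adjusted p = 0.00252), with the clock score as a covariate (adjusted p = 0.0342) or with array weights (adjusted p = 0.0444). Markers of stellate cells and fibroblasts had a mean of -0.09 (adjusted p = 0.0822) and passed without control 1, control 3, control 4, penicillin 2 or penicillin 4 (adjusted p from 0.015 to 0.047; mean -0.15 without control 1 and -0.16 without penicillin 4), while the mean was -0.022 without control 2, -0.06 without control 6, -0.019 without penicillin 1 and -0.033 without penicillin 3. This list also passed with no filter (adjusted p = 0.0176), a stricter filter (adjusted p = 0.0391) or the replicate block (adjusted p = 0.00842). Markers of hepatocytes had a mean of -0.00054 (adjusted p = 0.114, or 0.0341 with a trended and robust variance prior), with Ahsg at -0.14 and the fibrinogen chain Fgb at -0.13. Markers of endothelial cells (mean -0.07, adjusted p = 0.114; mean -0.022 without control 2, which stood at 0.27) and of T and NK cells (mean 0.08, adjusted p = 0.302; mean -0.01 without penicillin 6, which stood at 0.46, and 0.12 without control 2) did not pass. Those of B and plasma cells (mean 0.18, adjusted p = 0.57; mean 0.11 without control 1 and 0.12 without control 3) and erythroid cells (mean -0.02, adjusted p = 0.823; mean -0.09 without control 6) did not pass either. Nor did markers of adipocytes (adjusted p = 0.437), pancreatic acinar cells (adjusted p = 0.853) or skeletal muscle (adjusted p = 0.626). Cell cycle genes (mean 0.005, adjusted p = 0.638), one-carbon and choline metabolism (mean 0.00, adjusted p = 0.713) and circadian clock genes (mean 0.17, adjusted p = 0.57; mean 0.09 without penicillin 1, 0.11 without penicillin 5 and 0.29 without control 6) did not pass. Targets of AhR and Nrf2 (adjusted p = 0.638) had a mean of -0.04 (-0.02 without penicillin 1), a median of 0.01 and a test direction of lower. Genes that differ between male and female liver (adjusted p = 0.638) had a mean of -0.004, a median of 0.03 and a test direction of higher. The means of hepatocyte markers, cell cycle genes, one-carbon metabolism and these last genes lay so near 0 that their sign turned with single arrays omitted.

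**Figure D3:**
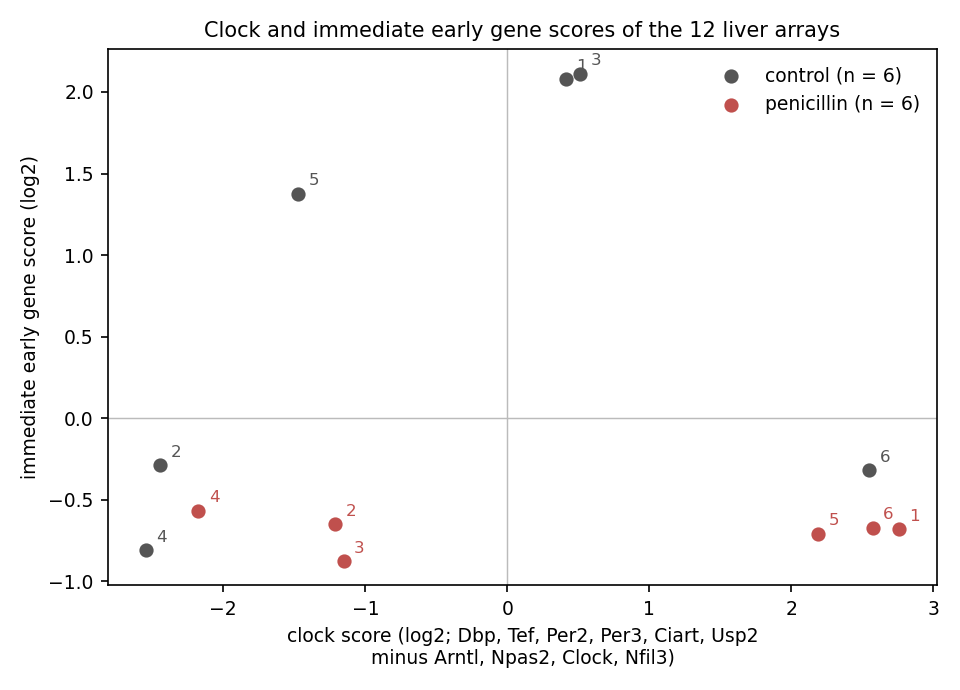
Clock score on the horizontal axis, the mean centred log2 level of Dbp, Tef, Per2, Per3, Ciart and Usp2 minus that of Arntl, Npas2, Clock and Nfil3, against the mean centred log2 level of the immediate early genes on the vertical axis; points are the 12 arrays, numbered by replicate. Control 6 and penicillin 1, 5 and 6 lie at clock scores of 2.19 to 2.76, and controls 1, 3 and 5 at immediate early scores of 1.38 to 2.11.

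By exact permutation tests of the 31 list means, the smallest exact p were 0.00649 for cholangiocyte markers, 0.00866 for CAR and PXR targets, and 0.0130 for both triglyceride storage and immediate early genes. Each of these had an adjusted exact p of 0.101. For fatty acid oxidation the exact p was 0.0260, with an adjusted exact p of 0.157.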

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

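Each group of 6 arrays was searched for a value far from the others, over most named genes, the 14 lists past the threshold and the array measures. Lists that did not pass were not searched, nor were Lpl, Scarb1, Igfbp1, Irs2, Ahsg, Fgb, Dbp and Arntl. Of 180 such groups of values 9 held one, which is the 1 in 20 that chance gives. No explanation was tested for these values.

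Control 6 stood apart in 3 of them. Its acute phase list mean was 1.38, where the next control was at 0.18. Its Icam1 level was 7.61 in log2 intensity, with the next control at 7.08. It also lay at 0.21 on the second principal component, along which the clock gene Dbp was positive, with the next control at -0.04. The other values were a Crp level of 13.05 in control 5, a Manf level of 11.29 in control 2, which was the lowest control, and a cholesterol synthesis list mean of -0.48 in control 4, also the lowest. Among penicillin arrays, Ptgds stood at 7.08 in penicillin 1, Saa1 at 10.54 in penicillin 6, and the 3-prime minus 5-prime signal of Gapdh at -0.017 in penicillin 3, each the highest of its group.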

How the results depend on the processing

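The fits with a clock or immediate early gene score and those without 3 or 4 arrays were chosen after the data were seen. No gene passed under any setting (0 by limma with each filter, normalization, variance prior, threshold, covariate and omitted array; 671 to 1244 genes at an unadjusted p under 0.05 with 1 array omitted). That count was 545 with the immediate early gene score as a covariate, where 5 lists were lower, and 488 without control 1, control 3 and control 5, where fewer samples were fitted. Lists past the threshold numbered 0 with an estimated correlation and 0 with fry, both of which allow for genes of a list moving together, and 14 after repeated quantile normalization or centring. With the stricter filter on dim probesets 6 lists passed as higher and 7 as lower. With 1 array omitted, lists shifted lower numbered 4 (without control 6) to 10 (without control 4). For cholesterol synthesis the mean turned to 0.10 with the immediate early gene score, where it passed as higher (adjusted p = 0.0396), and, without passing, to 0.046 without control 1, control 3 and control 5, and 0.0011 without the 4 arrays of high clock score (adjusted p = 0.283 and 0.944); for the interferon response it turned to -0.046 and -0.028 in the first 2 of these. Of single genes, none past the threshold over all genes, Acaca turned to -0.0028 without those 3 arrays and -0.0054 without the 4, Atf3, which had passed over its list alone, to 0.046 without the 3 and Scd1 to 0.0015 without the 4. With 1 array omitted Acaca ran from -0.021 to 0.053, Fasn from -0.043 to 0.21, Saa1 from -0.82 to 0.12 and Scd1 from -0.23 to -0.0012. The cause was not tested for any of these. Of the other values, 934 of genes kept their direction and side of the threshold. Of lists, 399 kept their side of the threshold, 37 fell short of it and 15 passed it. The direction of a list was compared only where the list had passed with all arrays. With the replicate block 1214 genes had an unadjusted p under 0.05 by limma, 0 passed (smallest adjusted p = 0.0732) and 14 lists passed. Arrays of 1 number correlated at -0.26 to 0.39, over 0.1 in 4 of 6 pairs, and 5 of 12 arrays correlated best with their own number. These values do not settle whether arrays of 1 number share a factor. No label says what a number stands for, so the main fit had no block. S100a8, at 4.74 with penicillin, lay near the filter of 4.73, where background limits how low a level can be read.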

Other observations

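The fits with a clock or immediate early gene score, the fits without arrays that stood apart and the test of blood content were chosen after the results they bear on were seen.

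Clock genes split the arrays across both groups. Dbp, an output gene of the circadian clock, stood at 10.27 ± 1.96 with penicillin and 9.25 ± 2.14 in controls (SD, n = 6), and Arntl, which peaks at the opposite phase, at 6.73 ± 1.64 and 7.10 ± 1.60, spreads far above those of most genes. A score of 6 genes that move with Dbp minus 4 that move with Arntl was 2.55 in control 6 and 2.76, 2.19 and 2.57 in penicillin 1, penicillin 5 and penicillin 6. It was 0.41 in control 1 and 0.51 in control 3, and lay between -2.54 and -1.15 in the other arrays. The group difference of the score was 0.99 (exact permutation p = 0.420, two-sided). Dbp and Arntl were chosen after their values were seen.

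Immediate early genes were lower in penicillin livers by 1.38 on the log2 scale. An unequal time of collection, read from clock genes, was tested as a cause. With the clock score as a covariate the difference was -1.47 (95% interval -2.77 to -0.17), so a straight-line relation to the score did not account for it. Such a covariate cannot remove a relation of another shape. Control 1 and control 3, with the highest immediate early means, had intermediate clock scores of 0.41 and 0.51. Time of collection is therefore not decided by this fit. Control 1, control 3 and control 5 carried high immediate early and heat shock genes together, so a different handling of these animals or livers may have raised both, but the labels give no order of collection and this was not tested. An effect of penicillin also stays open.

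Fatty acid oxidation genes were higher in penicillin livers by 0.26. With the clock score as a covariate the difference was 0.30 (95% interval 0.10 to 0.49), so a straight-line relation to the score did not account for it. A relation of another shape to time of collection was not tested. With the immediate early gene score it was 0.15 (95% interval -0.10 to 0.41), so handling and penicillin cannot be told apart for this list, since the interval held both 0 and the full difference and the score itself differed between the groups (exact permutation p = 0.0130). A response of lipid metabolism to penicillin stays open as a hypothesis.

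S100a8 and S100a9 were lower in penicillin livers by a mean of 1.79, of which the part of S100a8 is inexact, since its penicillin level of 4.74 lay near the filter of 4.73. Less blood in the penicillin pieces was tested with erythroid markers. Their difference was -0.016 (95% interval -0.23 to 0.20), far from that of the S100 genes, and was -0.09 without control 6. Only 3 of the 13 erythroid markers listed were measured, 1 higher and 2 lower, which limits this test. No single array carried the difference, which ran from -2.03 to -1.51 with 1 array omitted, the smallest without control 6. A lower number of neutrophils may be behind it, as a hypothesis, but the other neutrophil markers were not measured above the filter.

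The count of 950 genes at an unadjusted p under 0.05 was set against other splits of the 12 arrays. Of 100 splits drawn from 462, the real one included, 17 gave as many genes, with 1779 in the highest other, so chance is not excluded for this count. For the 14 lists past the threshold with camera's preset correlation, 2 of 100 splits gave as many, the highest other being 14. The share was under 0.05, which speaks against chance for this count but does not exclude it. With an estimated correlation 0 lists passed. The 14 splits that kept control 1, control 3 and control 5 on 1 side, the real one included, gave 6 to 14 lists (median 10.5), and the 86 others 1 to 12 (median 6), with both splits that reached 14 among the former. The count therefore does not separate treatment from whatever set those 3 arrays apart. In 4 splits at least 1 gene passed, with 304 genes in the split of control 1, 3 and 6 and penicillin 1, 5 and 6 from the rest, against 0 in the real split. The clock score differed by 3.67 across that split, which points to a structure of these samples along the clock genes rather than the treatment. With the clock score as a covariate 1196 genes had an unadjusted p under 0.05, and 0 passed (smallest adjusted p = 0.0726).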
